A study of Mus musculus with 112 samples.

How the data were processed

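The authors deposited gene counts and counts per M (CPM) for 112 single-end 3' RNA libraries (SC3-seq, 1 ng RNA per library, NextSeq 500). Their notes name cutadapt 3.0, STAR 2.7.9a on mm10, HTSeq 0.13.5 and DESeq2 1.30.1, and the annotation release and the use of strand in counting are not given in the sources used here. The deposited CPM equalled the deposited counts scaled to their library total to within 4.95e-10. The counts were therefore taken for every test. Of 32285 genes listed, 10560 had no count in any library and 127, with 0.00162% of the reads, had no symbol and were kept under their identifier. Gene coordinates in the text are those of GRCm38 in GENCODE M21.

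Sample groups were read from the titles and descriptions: cell type, age class, sex, replicate, animal and months. Paneth cells of each animal had been sequenced as 2 or 3 technical libraries, 69 in all, which were summed per animal. Libraries held 1.08 to 7.57 M counts. Per animal the ISC samples held 2.18 to 5.59 M, progenitors 2.48 to 7.57 M and Paneth cells 2.82 to 11.8 M, of which 1.09 to 5.68 M came from nuclear genes. The 10 most counted genes took 66.7% of Paneth, 10.8% of ISC and 8.35% of progenitor counts. Technical libraries of the same animal correlated at a median r of 0.637 over 66 pairs, those of other animals in the group at 0.601 over 501 pairs. Samples of different animals correlated at 0.905 in ISCs and 0.934 in progenitors.

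Age effects were tested in each cell type with 4 groups of age and sex, as the mean of the male and female difference, then within males, within females and as the difference of the differences. The sex effect was the mean of the young and aged difference, males against females. Paneth cells and progenitors were set against ISCs in young mice, and age effects were compared between cell types with all samples. Genes were kept by filterByExpr with a minimum count of 10, scaled by TMM and tested with the edgeR quasi-likelihood F test, with robust estimation, at Benjamini-Hochberg adjusted p below 0.05. Biological coefficients of variation were 0.433 in ISCs, 0.333 in progenitors and 0.706 in Paneth cells. Replicate numbers in the titles did not pair samples (median r of residuals 0.034, -0.0109 and -0.00188 in ISCs, progenitors and Paneth cells), so no block was used for them. Samples of the same animal are paired by origin, and across cell types their residuals correlated at 0.126, 0.169 and 0.17, so the animal was tried as a block in comparisons of cell types. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and data.table (1.17.8) were used. Expression is given as TMM-normalised CPM, mean ± SD over animals, and fold changes as log2 ± SE.

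A total of 27 gene lists were written from general knowledge before the counts were examined: ISC, Paneth, enterocyte, goblet, enteroendocrine, tuft, immune and stromal and endothelial markers, cell cycle, MHC class II presentation, MHC class I presentation, interferon response, antimicrobial and mucosal defence, NF-kB and inflammatory genes, Wnt targets and ligands, Notch pathway, fatty acid oxidation and PPAR targets, oxidative phosphorylation, mitochondrially encoded genes, cytosolic ribosomal proteins, unfolded protein response, cholesterol biosynthesis, p53 targets and senescence, regeneration-associated genes, xenobiotic metabolism, circadian clock, and dissociation stress and immediate early genes. Mitochondrially encoded and ribosomal lists were taken from gene names. Symbols found were 58 of 69 for oxidative phosphorylation, 49 of 52 for interferon genes, 31 of 32 for immune markers, 24 of 26 for Paneth markers, 22 of 24 for regeneration-associated genes and 18 of 19 for circadian genes, and all for the others. Lists with at least 5 measured members were tested by camera with a preset inter-gene correlation of 0.01, with camera at a correlation estimated per list, and with fry. Camera with the preset value takes genes of a list as nearly independent, so its p-values are optimistic where members move together, and the value with an estimated correlation is printed beside it where a call is lost. Stromal and endothelial markers had fewer than 5 measured members in every comparison and immune markers in ISCs and progenitors alone, so their summed CPM was compared by permutation of age within sex. Genes past the threshold "within the list" were adjusted over the list alone.

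Genes named in the text were chosen by rules fixed before the results were seen. In each age effect these took the 6 largest changes in each direction among called genes of at least 5 CPM on average with the same sign in both sexes, and in the other comparisons the 4 largest in each direction. Unnamed gene models and pseudogenes were passed over. Up to 4 members with the smallest p were added for each list that passed camera or held at least 2 called genes, and Lgr5, Olfm4, Lyz1, Mki67, Cd74, Xist and Ddx3y throughout. Alternatives to the scaling, the filter, the tool, the block, the covariates and the samples were fixed beforehand as well. For the cell type and sex comparisons the rule on lists was narrowed for a time after the alternatives had been seen, and was then put back, so that every gene it names was tested; 4 of these genes are not reported here. A pair was added after the data had been seen: leaving out mitochondrially encoded genes, and leaving out the ISC library richest in immune markers. Negative binomial counts simulated from the mean share, trended dispersion and library sizes of the data, with 200 planted changes, gave 9 wrong calls of 136 in the ISC age effect, 3 of 143 in progenitors, 1 of 67 in Paneth cells, 1 of 87 in Paneth cells against ISCs, and 9 of 146 and 8 of 115 in the comparisons of age effects between cell types. Planted 1.5-fold, 2-fold and 4-fold changes were recovered in 32.8, 62.7 and 95.5% in ISCs, 34.3, 82.1 and 93.9% in progenitors and 4.48, 23.9 and 71.2% in Paneth cells. In Paneth cells against ISCs these shares were 8.96, 44.8 and 75.8%. Planted differences of 1.17, 2 and 4 log2 units between age effects were recovered in 46.3, 65.7 and 93.9% for progenitors against ISCs and 17.9, 55.2 and 87.9% for Paneth cells against ISCs.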

Results

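Gene expression was compared between young (2 to 3 months) and aged (23 to 27 months) mice in 3 sorted populations of the proximal small intestine. Intestinal stem cells (ISCs) were Lgr5-GFP high and progenitors GFP medium to low, both Epcam high and CD24 low. Paneth cells were CD24 high, side-scatter high and GFP negative. After the technical Paneth libraries of each animal were summed, 23 ISC, 20 progenitor and 24 Paneth samples of both sexes remained, under 36 animal names. For 2 of these names, counted apart here, whether they are the same aged male is not given in the sources used here. Xist set against the Y-linked gene Eif2s3y placed every one of the 23, 20 and 24 samples in its stated sex. Counts per animal had a median of 4.06 M in ISCs, 4.83 M in progenitors and 7.11 M in Paneth cells. Transcripts of the mitochondrial genome took 56.6 ± 10.2% of the Paneth counts, against 5.94 ± 1.74% in ISCs and 4.3 ± 1.33% in progenitors (mean ± SD). In Paneth cells this share was lower in aged mice (51.6 ± 10.9% against 61.6 ± 6.74%, n = 12 and 12). Within sex the difference was -10.5 points (permutation test p = 0.00911, adjusted permutation p = 0.0273). ISC and progenitor shares did not pass (adjusted permutation p = 0.37 and 0.692).

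**Figure D1:**
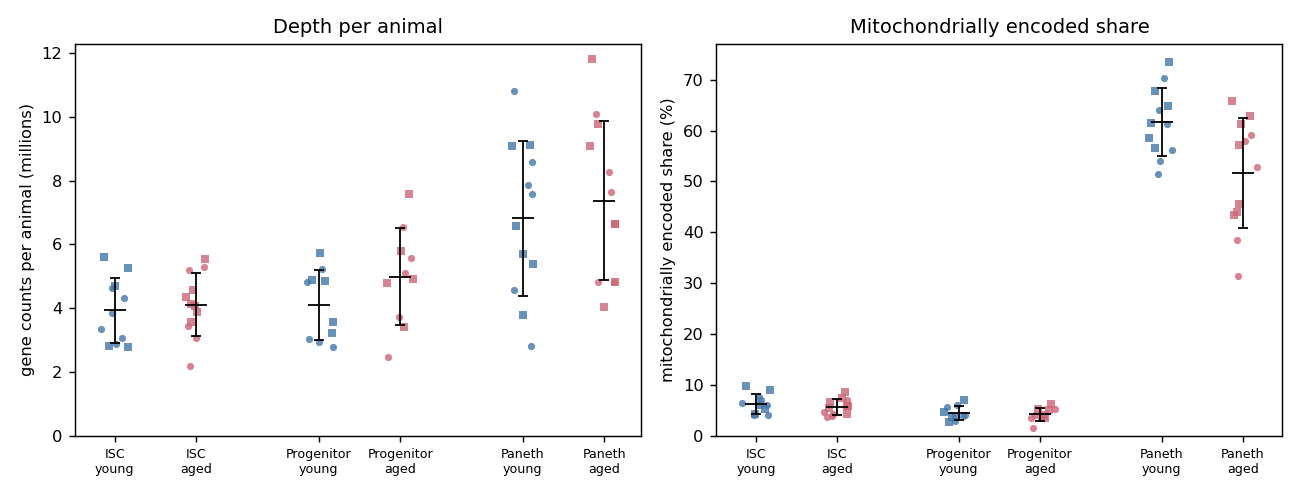
Gene counts per animal in M (left) and share of counts from mitochondrially encoded genes in % (right), by cell type and age; each point is 1 animal (squares male, circles female, blue young, red aged) and bars are mean ± SD. The Paneth share averaged 61.6% in young and 51.6% in aged mice.

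How far did the sorted populations differ in young mice? Paneth cells carried the lysozyme gene Lyz1 (ENSMUSG00000069515, chromosome 10, 117287797 to 117292868), the antimicrobial product of their granules, above ISCs (log2 fold change 8.58 ± 0.34, estimate ± SE, edgeR adjusted p = 1.42e-17, n = 12 and 11). Of 12376 genes, 2178 were higher and 1585 lower in Paneth cells. Afp, Sst and Rac2 were among the genes furthest apart (log2 11.48, 10.93 and 10.54), with ISC means of 0.0662, 0.103 and 0.0195 CPM. Of 22 Paneth cell markers 21 were higher, with Itln1, Mmp7 and Defa21 (log2 8.80, 7.63 and 9.21, highest edgeR adjusted p = 4.60e-16). That list had a median of 8.44 (camera adjusted p = 2.03e-70, and adjusted p = 1.08e-05 with an estimated correlation). The Defa genes form a multigene family, so reads of Defa21 are assigned with uncertainty. Olfm4, Lgr5, Smoc2 and Gkn3 (log2 -1.76, -1.11, -1.08 and -1.75, highest edgeR adjusted p = 0.000245) were lower. So were 19 of 24 ISC markers (median -1.01, camera adjusted p = 1.64e-11, adjusted p = 0.00905 with an estimated correlation). Lgr5 fell less than in progenitors, so carry-over of ISCs is not excluded. Cell cycle genes were lower in 35 of 41 cases, among them Mki67, Ube2c and Aurkb (log2 -0.77, -1.18 and -1.36, highest edgeR adjusted p = 0.000131). The list had a median of -0.99 (camera adjusted p = 3.46e-19). Xrcc2, Parpbp, Esr1 and Fgr fell furthest among the named genes (log2 -2.93, -2.78, -2.78 and -2.62). All 8 measured transcripts of the mitochondrial genome were higher, mt-Co1 by 4.20 ± 0.16 (edgeR adjusted p = 3.72e-22, list median 5.26, camera adjusted p = 4.38e-49). Unfolded protein response genes, which serve secretory cells, were higher in 24 of 29 cases, with Dnajc3, Ern2 and Edem1 (log2 2.11, 5.06 and 2.34, highest edgeR adjusted p = 5.38e-12). Their median was 1.01 (camera adjusted p = 3.70e-14).

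Markers of further lineages were also higher in the Paneth gate of young mice, a gate in which CD24-positive enteroendocrine and tuft cells can fall. All 15 tuft markers were higher, with Dclk1, Sh2d6 and Alox5ap (log2 9.97, 9.99 and 8.33, highest edgeR adjusted p = 1.16e-14). Their median was 7.11 (camera adjusted p = 1.42e-20). Of 17 enteroendocrine markers 16 were higher, with Chga, Sct and Gip (log2 7.68, 4.52 and 10.22, highest edgeR adjusted p = 5.63e-08) and a list median of 5.77 (camera adjusted p = 1.29e-09). All 17 goblet markers, 18 of 22 enterocyte markers and 8 of 12 immune markers were higher. Their medians were 2.68, 3.00 and 6.10 (camera adjusted p = 1.36e-28, 4.10e-33 and 8.94e-08), with Muc2, Apoa4 and Igkc among them (log2 4.41, 5.40 and 5.68, highest edgeR adjusted p = 5.86e-10). Xenobiotic genes were higher in 16 of 28 cases, Gsta1 by 7.19 (median 1.35, camera adjusted p = 9.15e-10). Regeneration-associated genes were higher in 6 of 11, Anxa2 by 1.65 (median 0.84, camera adjusted p = 0.00709). Wnt targets fell in 10 of 21 cases, with Ascl2 (log2 -1.28, edgeR adjusted p = 7.56e-05). That list lost its call when correlation was estimated (median -0.72, camera adjusted p = 0.0238, adjusted p = 0.245 with an estimated correlation). Cd74 did not pass (-0.22, edgeR adjusted p = 0.38), nor did the MHC class II list (median -0.33, camera adjusted p = 0.264). The median fold change of all genes was -1.86 when totals were left unscaled, so directions here are relative to the typical gene. Then 11044 genes were called, with 3.59% rather than 57.9% higher. In that unscaled comparison Ly6e (0.84 scaled), Krt7 (0.62 scaled) and Calr (1.27 scaled) turned to -1.05, -1.26 and -0.62.

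Progenitors of young mice had lost most of the stem cell programme. Lgr5 (ENSMUSG00000020140, chromosome 10, 115450311 to 115587780), whose GFP reporter defined the gates, stood at 4.7 ± 3.47 CPM against 104 ± 17.3 CPM in ISCs (log2 -4.53 ± 0.30, edgeR adjusted p = 1.80e-16, n = 10 and 11). Olfm4 changed by -2.86 ± 0.14 (edgeR adjusted p = 1.70e-20). Of 12376 genes 1621 were higher and 1385 lower (1045 and 572 with the animal as block). ISC markers were lower in 23 of 24 cases, with Gkn3, Smoc2, Tnfrsf19 and Axin2 (log2 -3.75, -1.66, -4.35 and -2.37, highest edgeR adjusted p = 2.99e-11). Their median was -1.83 (camera adjusted p = 1.16e-44). Wnt targets were lower in 13 of 21 cases (median -1.93, camera adjusted p = 1.07e-14). Fstl1 and Slc1a2 were also lower (log2 -4.68 and -4.63). Absorptive and secretory genes were higher together. All 17 goblet markers were higher, with Muc2, Zg16 and Agr2 (log2 4.94, 6.71 and 4.25, highest edgeR adjusted p = 8.61e-12), at a median of 4.23 (camera adjusted p = 2.82e-53). So were 16 of 22 enterocyte markers (median 1.76, camera adjusted p = 5.78e-27). Rbp2, Lct and, outside the list, Slc6a19 rose (log2 4.35, 6.31 and 7.48, highest edgeR adjusted p = 1.36e-12). Enteroendocrine markers were higher in 14 of 17, with Chga, Chgb and Gcg (log2 4.71, 4.76 and 4.77, highest edgeR adjusted p = 2.72e-05) and a median of 4.29 (camera adjusted p = 8.25e-09). Unfolded protein response, cholesterol biosynthesis and xenobiotic genes were higher in 21 of 29, 17 of 22 and 21 of 28 cases (medians 1.12, 1.02 and 1.36, camera adjusted p = 1.00e-15, 3.50e-08 and 3.40e-15). Xbp1, Fdps and Gsta1 were among them (log2 1.32, 1.10 and 7.32, highest edgeR adjusted p = 1.54e-05). Antimicrobial genes were higher in 9 of 15 (median 1.13, camera adjusted p = 0.000307). Reg3a, Reg3g and the Paneth marker Ang4 rose (log2 3.88, 2.06 and 2.29, highest edgeR adjusted p = 3.56e-05).

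Several progenitor lists passed camera but not when correlation was estimated. Cell cycle genes were lower in 14 of 41 cases, with Top2a, Cenpf and Bub1b (log2 -0.61, -1.01 and -0.78, highest edgeR adjusted p = 0.00104). Their list had camera adjusted p = 0.00072, and adjusted p = 0.147 with an estimated correlation, while Mki67 did not pass (-0.29, edgeR adjusted p = 0.208). Oxidative phosphorylation was higher in 34 of 58 genes, Sdhb by 0.69 (camera adjusted p = 5.23e-08, adjusted p = 0.137 with an estimated correlation). Ribosomal proteins were lower in 40 of 79, Rpl5 by -0.66 (camera adjusted p = 1.86e-06, adjusted p = 0.316 with an estimated correlation). MHC class I (11 of 22 higher), interferon (9 of 38), fatty acid oxidation (11 of 29) and Paneth markers (7 of 22) had camera adjusted p = 0.00457, 0.00199, 0.0407 and 0.0398. These became adjusted p = 0.185, 0.147, 0.297 and 0.544 with an estimated correlation. Lyz1 was higher by 0.71 ± 0.25 (edgeR adjusted p = 0.0346). That call ended in 8 of 33 fits that left out 1 sample (highest edgeR adjusted p = 0.0676, without progenitor young female replicate 2). Cd74 did not pass (-0.42, edgeR adjusted p = 0.11). Xist in males and Ddx3y in females lay at the floor of counting, so these genes are followed only in the sex that expresses them.

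Which genes change with age in ISCs? Ly6e (ENSMUSG00000022587, chromosome 15, 74955051 to 74959905), which encodes an interferon-inducible surface protein with a glycosylphosphatidylinositol anchor, rose from 357 ± 53.5 to 1135 ± 158 CPM (log2 fold change 1.68 ± 0.091, 3.2-fold, edgeR adjusted p = 1.89e-16, n = 12 aged and 11 young). Ceacam10 (ENSMUSG00000054169, chromosome 7, 24777206 to 24784657), of the carcinoembryonic antigen family, rose from 61.8 ± 23.8 to 283 ± 102 CPM (2.11 ± 0.24, edgeR adjusted p = 2.24e-05). Slc28a2 (ENSMUSG00000027219, chromosome 2, 122426477 to 122461137), which encodes a concentrative transporter of purine nucleosides, fell from 53.3 ± 27.2 to 4.58 ± 4.85 CPM (-3.47 ± 0.42, edgeR adjusted p = 2.24e-05). Nrn1 (ENSMUSG00000039114, chromosome 13, 36725361 to 36735131), which encodes neuritin, fell by 1.43 ± 0.27 (edgeR adjusted p = 0.00404) and was the only one of 24 ISC markers called. In all 34 genes rose and 8 fell of 11958 tested. Risers also included Fam20a, Foxd2os and Zfp990 (log2 1.66, 4.95 and 7.11, edgeR adjusted p = 0.000137, 2.17e-06 and 0.0026). Foxd2os and Zfp990 were close to 0 in young ISCs (0.374 and 0.0363 CPM, against 11.2 and 10.3 CPM in aged ISCs). The fallers included Wfdc2 and Cdc42bpg (log2 -2.09 and -0.95, edgeR adjusted p = 0.00652 and 0.0312). Foxd2os (ENSMUSG00000085399, chromosome 4, 114909257 to 114921967) is an antisense transcript. Zfp990 (ENSMUSG00000078503, chromosome 4, 145510759 to 145539188) belongs to a zinc finger gene family, so the reads of each are assigned with uncertainty. Zfp990 exceeded the young median in 7 of 12 aged animals and did not pass limma-voom (adjusted p = 0.318). The stem cell genes Lgr5 (-0.20) and Olfm4 (0.18), the proliferation gene Mki67 (-0.18), Lyz1 (0.018) and Cd74 (0.30) did not pass (edgeR adjusted p = 0.646, 0.517, 0.86, 0.996 and 0.811). DESeq2 called more ISC genes than edgeR (1.1e+02 against 42). Cdc42bpg kept no call in 8 of 23 fits that left out 1 animal (highest edgeR adjusted p = 0.0754, without ISC young female replicate 5). Wfdc2 ended at -1.85 (edgeR adjusted p = 0.0501) without the animals of 26 and 27 months.

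Of the lists on defence and antigen presentation, only the antimicrobial list kept its call in aged ISCs when correlation was estimated. Antimicrobial and mucosal defence genes, which include the oxidase Duox2 and the inducible nitric oxide synthase Nos2, had a median of 0.70 over 13 genes (camera adjusted p = 4.73e-05 and adjusted p = 0.0379 with an estimated correlation). Duox2, Nos2, Cd14 and Pigr (log2 0.97, 1.60, 0.77 and 0.23, edgeR adjusted p = 0.0588, 0.0713, 0.208 and 0.312) did not pass over all genes, and 4 members passed within the list alone. All 8 MHC class II genes leaned upward (median 0.60, camera adjusted p = 3.77e-07 and adjusted p = 0.121 with an estimated correlation). H2-DMb1, H2-DMa, H2-Aa and Ciita (log2 0.67, 0.62, 0.95 and 0.84, edgeR adjusted p = 0.136, 0.143, 0.179 and 0.247) did not pass over all genes, and 4 members passed within the list. Of 21 MHC class I genes 18 leaned upward and 7 passed within the list (median 0.33, camera adjusted p = 1.03e-06 and adjusted p = 0.138 with an estimated correlation). The immunoproteasome genes Psmb8 and Psmb9 leaned upward without passing over all genes (0.71 and 0.72, edgeR adjusted p = 0.0887 and 0.174). Dissociation stress genes (Fos 1.26, Junb 0.93, edgeR adjusted p = 0.0588 and 0.16) had a median of 0.42 (camera adjusted p = 8.88e-05 and adjusted p = 0.196 with an estimated correlation). The summed immune markers were 17.5 ± 6.05 CPM in young and 52.3 ± 122 CPM in aged ISCs (permutation test p = 0.234). Aged female replicate 2 carried 440 CPM, 251 of it Igkc and 166 Igha, and the next animal 36.9 CPM. Without that library the medians became 0.434 for MHC class II, 0.261 for MHC class I, 0.267 for stress and 0.415 for antimicrobial genes, and the count of called genes stayed at 42. Stromal and endothelial markers summed to 6.24 ± 3.75 CPM in young and 8.09 ± 5.43 CPM in aged ISCs.

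In the xenobiotic list the alcohol dehydrogenase gene Adh1 (0.77 ± 0.14, edgeR adjusted p = 0.00492) and the cytochrome P450 gene Cyp2c65 (0.74 ± 0.15, edgeR adjusted p = 0.0118) rose with age in ISCs. The other 20 of 22 members did not pass (median 0.28, camera adjusted p = 0.0026 and adjusted p = 0.153 with an estimated correlation). Cyp2c65 lost its call without the animals of 26 and 27 months at a similar fold (0.666, edgeR adjusted p = 0.0938). Top2a and Mcm3 (log2 -0.35 and -0.35, edgeR adjusted p = 0.174 and 0.175) did not pass, nor did any cell cycle gene, while the list leaned lower (median -0.085, camera adjusted p = 0.0399 and adjusted p = 0.196 with an estimated correlation). Enteroendocrine markers (5 measured, median 0.70), NF-kB genes (0.38), oxidative phosphorylation (0.073), interferon genes (0.18) and unfolded protein response (0.056) leaned upward and mitochondrial transcripts (-0.21) downward. None of their members was called (camera adjusted p = 0.0244, 0.0026, 0.00748, 0.046, 0.0474 and 0.0474). With an estimated correlation they had adjusted p = 0.196, 0.121, 0.603, 0.427, 0.239 and 0.61. Regeneration-associated genes passed as higher (camera adjusted p = 0.046 and adjusted p = 0.153 with an estimated correlation), with Ly6e the only member called, although their median (-0.065) and mean (-0.16) lay below 0. ISC markers, Paneth markers, goblet markers, tuft markers, Wnt, Notch, ribosomal, cholesterol and circadian lists did not pass (camera adjusted p = 0.347, 0.347, 0.204, 0.564, 0.844, 0.434, 0.347, 0.791 and 0.944). Nor did enterocyte markers (median 0.033 with camera pointing down), fatty acid oxidation (0.0044 against a mean of -0.024) or p53 targets (-0.028 against a mean of 0.079, camera adjusted p = 0.941, 0.841 and 0.648).

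**Figure D2:**
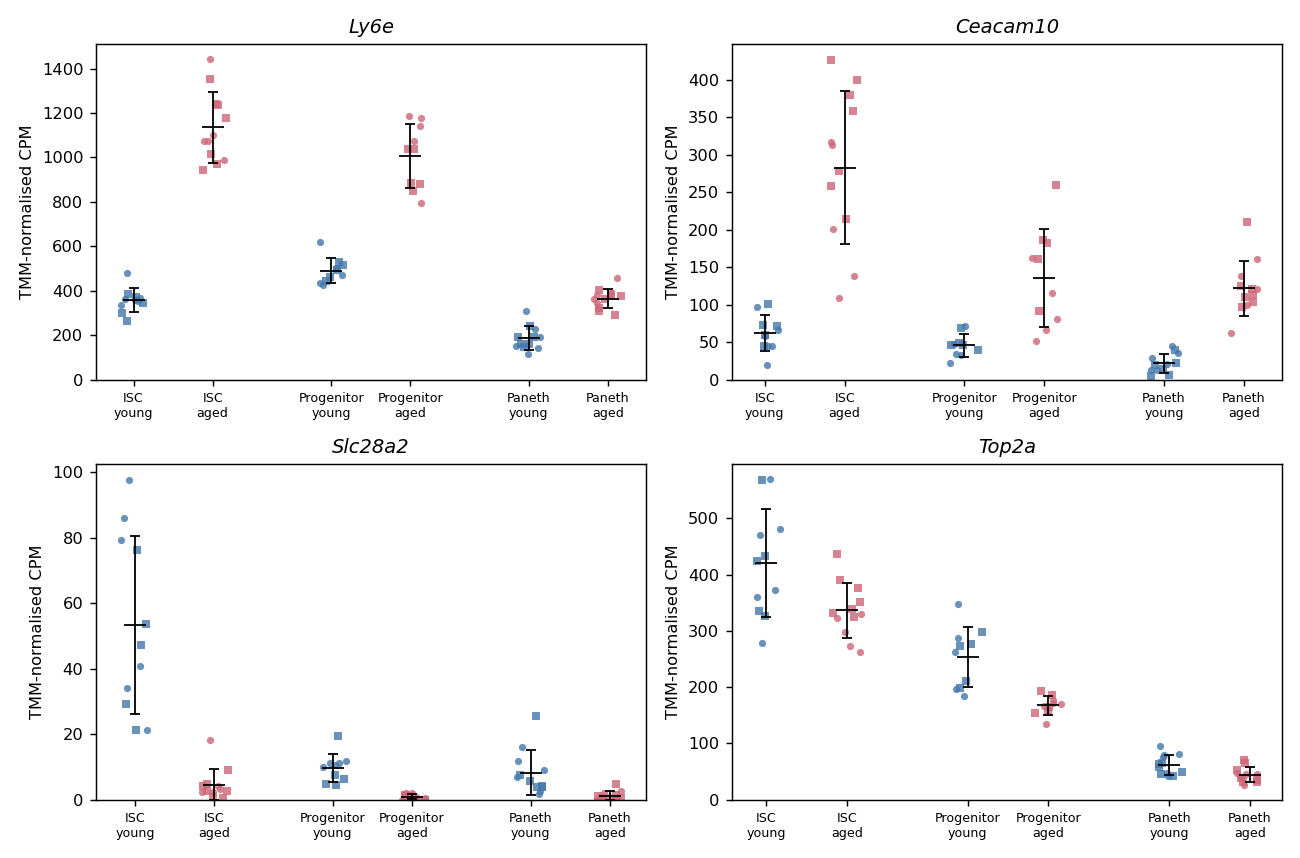
Expression of Ly6e, Ceacam10, Slc28a2 and Top2a in TMM-normalised CPM (y axis) by cell type and age (x axis); each point is 1 animal and bars are mean ± SD. Ly6e rose from 357 to 1135 CPM in ISCs and from 490.1 to 1006 CPM in progenitors.

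In progenitors, did the same genes change? Ly6e rose from 490.1 ± 57.6 to 1006 ± 144.2 CPM (1.03 ± 0.088, edgeR adjusted p = 1.83e-09, n = 10 and 10). Ceacam10 and Psmb8 (log2 1.504 and 0.76, edgeR adjusted p = 0.000756 and 0.000917) rose with it. Nrn1 fell by 3.05 ± 0.40 and Slc28a2 by 3.47 ± 0.51 (edgeR adjusted p = 3.33e-05 and 0.000174). Of 11812 genes 55 rose and 31 fell, with 64% higher (53.1% with unscaled totals). Serpinb5 (ENSMUSG00000067006, chromosome 1, 106861173 to 106883348), which encodes maspin, rose by 2.65 ± 0.45 (edgeR adjusted p = 0.00107). Fmo1, Iyd and Atf3 (log2 1.74, 1.73 and 2.08, edgeR adjusted p = 0.0147, 0.0166 and 0.0203) rose too. BC049987, Trip6, Prkd3 and Lipo3 (log2 -1.70, -1.61, -1.40 and -1.03, edgeR adjusted p = 0.0308, 0.0398, 0.0191 and 0.0251) fell. Several cell cycle genes were lower in aged progenitors. Top2a (ENSMUSG00000020914, chromosome 11, 98992943 to 99024189), which encodes DNA topoisomerase II alpha, went from 254 ± 53.2 to 168 ± 16.7 CPM (-0.60 ± 0.11, edgeR adjusted p = 0.00198). Ube2c, Aurka and Cdc45, which act in mitosis and replication, fell with it (log2 -0.52, -0.58 and -0.51, edgeR adjusted p = 0.00304, 0.00638 and 0.0281). Of 41 cell cycle genes 6 fell over all genes, 18 passed within the list alone and 38 leaned lower. The list was called with the preset correlation and by fry (median -0.33, camera adjusted p = 2.16e-20 and adjusted p = 0.0532 with an estimated correlation, fry adjusted p = 0.00711). Mki67 did not pass (-0.39, edgeR adjusted p = 0.123). Lgr5 (-0.29), Olfm4 (-0.19), Lyz1 (0.49) and Cd74 (0.26) did not pass either (edgeR adjusted p = 0.925, 0.635, 0.749 and 0.805). Without the 3 males of 26 and 27 months the count fell from 86 to 34, while DESeq2 called 130 with all animals. Top2a, Aurka, Iyd, Prkd3, Lipo3, Trip6 and BC049987 then lost their calls at log2 -0.56, -0.50, 1.61, -1.39, -1.04, -1.75 and -1.76 (edgeR adjusted p = 0.0552, 0.128, 0.108, 0.151, 0.109, 0.141 and 0.0689). Cdc45 and Atf3 lost theirs at smaller values (-0.384 and 1.04, edgeR adjusted p = 0.394 and 0.692). The description covariate ended the same calls except that of Top2a, and limma-voom those of Fmo1, Prkd3, Atf3, BC049987 and Trip6. Fits that left out 1 animal ended the call of Atf3 in 2 of 20 (highest edgeR adjusted p = 0.0689, without aged male replicate 1) and of Lipo3 in 6 (0.0662, without young male replicate 5). They ended that of BC049987 in 9 (highest edgeR adjusted p = 0.0818, without young female replicate 3) and of Trip6 in 13 (0.118, without young male replicate 3). Prkd3 was lost in 1 (edgeR adjusted p = 0.0543, without young female replicate 1) and Cdc45 in 8 (0.0645, without young male replicate 4).

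The enteroendocrine genes Tac1 and Sct rose in aged progenitors. Tac1 (ENSMUSG00000061762, chromosome 6, 7554879 to 7565834), the precursor gene of substance P, went from 14.1 ± 9.05 to 54.8 ± 33 CPM (1.96 ± 0.44, edgeR adjusted p = 0.0483). The secretin gene Sct rose by 0.75 ± 0.17 (edgeR adjusted p = 0.0227), while the granin genes Chga and Chgb did not pass (1.40 and 1.56, edgeR adjusted p = 0.112 and 0.112). All 17 measured enteroendocrine markers leaned upward and 9 passed within the list (median 1.07, camera adjusted p = 1.40e-10 and adjusted p = 0.102 with an estimated correlation, fry adjusted p = 0.0446). Goblet and tuft markers did not pass (medians -0.020 and 0.35, camera adjusted p = 0.595 and 0.558). Tac1 lost its call in 16 of 20 fits that left out 1 animal (highest edgeR adjusted p = 0.109, without young male replicate 3) and Sct in 4 (highest 0.0599, without aged male replicate 4). Of 28 xenobiotic genes Ces1f, Cyp2b10 and Cyp2d26 rose (log2 0.78, 2.60 and 0.87, edgeR adjusted p = 0.00198, 0.0251 and 0.0398). Within the list 10 passed (median 0.44, camera adjusted p = 1.95e-10 and adjusted p = 0.145 with an estimated correlation). The pantetheinase gene Vnn1 rose in the fatty acid list (1.40, edgeR adjusted p = 0.00392). That list had a median of 0.10 (camera adjusted p = 0.00378 and adjusted p = 0.399 with an estimated correlation). Cyp2b10 was lost in 6 and Cyp2d26 in 12 of 20 such fits (highest edgeR adjusted p = 0.0602 and 0.113, without aged male replicates 3 and 2). H2-DMb1 rose by 0.87 (edgeR adjusted p = 0.00392) in the MHC class II list (median 0.45, camera adjusted p = 8.57e-06 and adjusted p = 0.162 with an estimated correlation). Psmb8 was the member of the MHC class I list to pass (median 0.18, camera adjusted p = 2.31e-05 and adjusted p = 0.162 with an estimated correlation). Atf3 and Fosb rose among stress genes, Fosb by 2.09 (edgeR adjusted p = 0.0308). Fosb was lost in 11 of 20 fits (highest edgeR adjusted p = 0.158, without aged female replicate 4). Without the males of 26 and 27 months Tac1, Cyp2b10, Cyp2d26, Fosb and Vnn1 lost their calls (log2 1.77, 2.34, 0.802, 2.04 and 1.28, edgeR adjusted p = 0.335, 0.226, 0.248, 0.165 and 0.0715). The description covariate ended these and that of Sct (edgeR adjusted p = 0.0647). Unscaled totals ended those of Tac1 and Cyp2d26, either other filter that of Tac1, and limma-voom those of Tac1, Cyp2b10, Cyp2d26 and Fosb. The stress list had a median of 0.21 (camera adjusted p = 3.18e-05 and adjusted p = 0.154 with an estimated correlation).

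The remaining progenitor lists that passed camera moved by small amounts. Oxidative phosphorylation (0.11), ribosomal proteins (0.11), regeneration-associated genes (0.091, Ly6e alone called), enterocyte markers (0.18) and NF-kB genes (0.27) leaned upward. ISC markers (-0.099, Nrn1 alone called) and interferon genes (-0.097) leaned downward. Their camera adjusted p = 2.72e-06, 4.54e-06, 0.00297, 0.00386, 0.017, 0.0236 and 0.0387 in this order. With an estimated correlation these had adjusted p = 0.361, 0.399, 0.162, 0.399, 0.163, 0.386 and 0.399. The antimicrobial list, called in ISCs, did not pass in progenitors (median 0.13, camera adjusted p = 0.292). Mitochondrial transcripts (-0.085, camera adjusted p = 0.26) and p53 targets (0.18, camera adjusted p = 0.0889) did not pass, nor did Paneth markers, whose median (0.047) and test differed in sign (camera adjusted p = 0.438). Stromal and endothelial markers were higher in the aged progenitor samples (48.2 ± 32.8 against 21.5 ± 7.87 CPM, permutation test p = 0.007, adjusted permutation p = 0.042). Immune markers were not (17.3 ± 5.81 against 14.9 ± 2.49 CPM, permutation test p = 0.248).

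**Figure D3:**
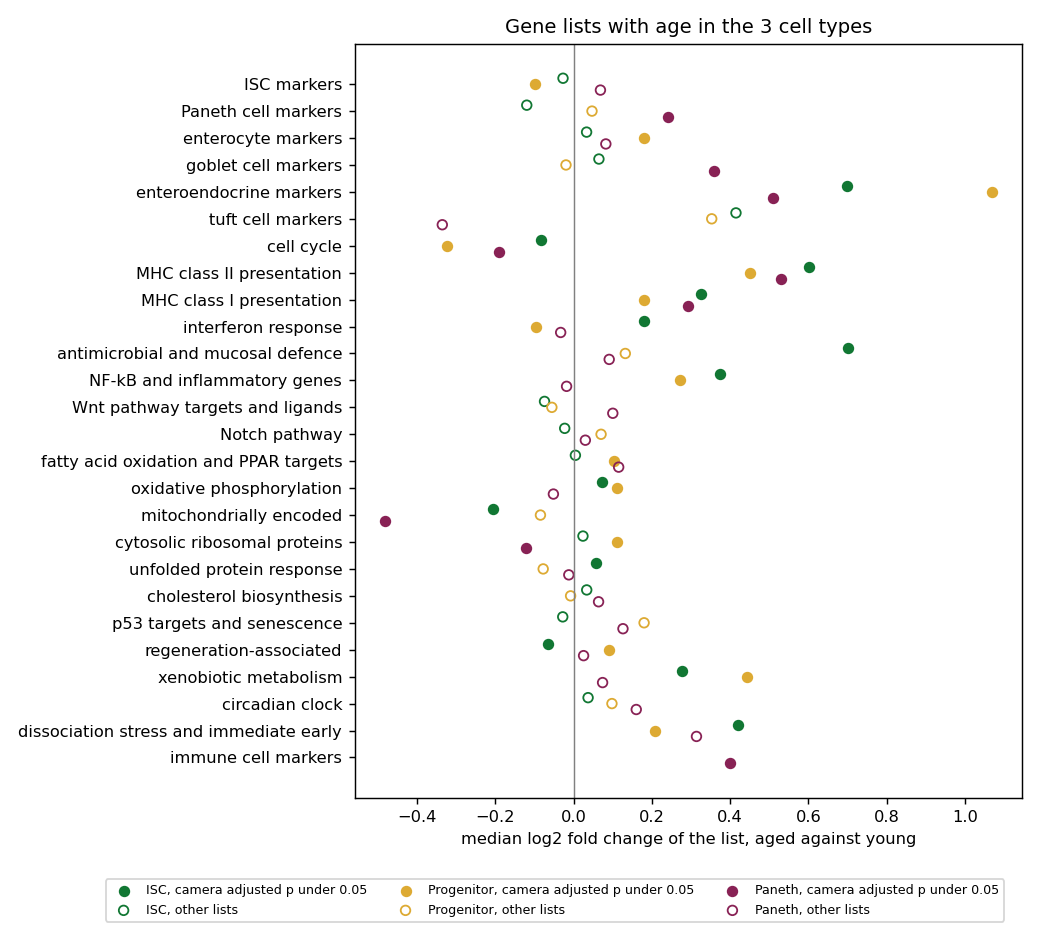
Median log2 fold change, aged against young, of each gene list (y axis) in ISCs, progenitors and Paneth cells; filled points have camera adjusted p under 0.05, open points do not. In progenitors cell cycle genes lay at -0.325 and enteroendocrine markers at 1.07.

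Paneth cells changed in fewer genes. Ceacam10 rose from 21.8 ± 12.9 to 122 ± 36.9 CPM (2.49 ± 0.26, edgeR adjusted p = 4.07e-07). Ly6e rose from 186 ± 53.4 to 364 ± 44.9 CPM (0.98 ± 0.13, edgeR adjusted p = 2.49e-05, n = 12 and 12). Dmbt1 (ENSMUSG00000047517, chromosome 7, 131032053 to 131121630), which encodes a mucosal scavenger receptor glycoprotein, fell by 0.59 ± 0.11 (edgeR adjusted p = 0.0198). AI427809, Tmed6 and Pnliprp2 (log2 2.19, 0.99 and 0.70, edgeR adjusted p = 0.0199, 0.0231 and 0.0404) rose. In all 7 genes rose and 1 fell of 11663. Paneth markers leaned upward in 17 of 22 cases, with Pnliprp2 called and Lyz1 not (0.49 ± 0.16, edgeR adjusted p = 0.367). Their median was 0.24 (camera adjusted p = 0.00089 and adjusted p = 0.565 with an estimated correlation). Over all genes H2-Aa and H2-Ab1 did not pass (log2 0.85 and 0.65, edgeR adjusted p = 0.162 and 0.207), while 5 of 8 MHC class II genes passed within their list (median 0.53, camera adjusted p = 8.59e-06 and adjusted p = 0.31 with an estimated correlation). MHC class I genes leaned upward too, with Psmb8 at 0.76 (edgeR adjusted p = 0.0588) and a median of 0.29 (camera adjusted p = 0.00139 and adjusted p = 0.552 with an estimated correlation). All 9 mitochondrial transcripts leaned downward, mt-Cytb by -0.52 (edgeR adjusted p = 0.412). Their median was -0.48 (camera adjusted p = 1.09e-05 and adjusted p = 0.552 with an estimated correlation). Ribosomal proteins (-0.12) and cell cycle genes (-0.19) lay lower and goblet (0.36), enteroendocrine (0.51) and immune markers (0.40) higher. They passed camera (camera adjusted p = 0.00139, 0.00172, 0.00409, 0.0202 and 0.0328, and adjusted p = 0.656, 0.565, 0.565, 0.565 and 0.565 with an estimated correlation). No other list passed. ISC markers, NF-kB genes and Notch genes had medians (0.068, -0.018 and 0.030) opposite in sign to their test or mean. So had regeneration-associated genes (median 0.025, mean -0.28) and enterocyte markers (median 0.082, mean -0.10). Lgr5 (-0.64), Mki67 (-0.30), Cd74 (0.29) and Olfm4 (0.14) did not pass (edgeR adjusted p = 0.722, 0.798, 0.786 and 0.928). The summed immune markers were 96.1 ± 58.5 CPM in young samples and 32 CPM higher within sex in aged samples (permutation test p = 0.18). Stromal markers were 31.2 ± 25.7 CPM in aged and 13.8 ± 12.1 CPM in young samples (permutation test p = 0.0587).

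The Paneth comparison had the least power. Of planted 2-fold changes, 23.9% were recovered there, against 62.7% in ISCs and 82.1% in progenitors, so changes of that size are often missed in Paneth cells. DESeq2 called 36 genes, unscaled totals 22 (with the median of all genes shifted by 0.235), the first technical library alone 3, and samples without the animals of 26 and 27 months 2, where Dmbt1, AI427809, Tmed6 and Pnliprp2 lost their calls at similar folds (-0.608, 2.31, 0.901 and 0.577, edgeR adjusted p = 0.0559, 0.0559, 0.178 and 0.28). Dmbt1 also lost its call with unscaled totals (-0.37, edgeR adjusted p = 0.415), the first technical library alone (-0.491, 0.263) and the title number as block (-0.567, 0.0613). Leaving out aged female replicate 1, young female replicate 4 or young female replicate 6 gave 3, 5 and 13 genes. Without young female replicate 4 Dmbt1 reached edgeR adjusted p = 0.0698, a call it lost in 2 of 24 such fits. Without aged female replicate 1 AI427809 reached edgeR adjusted p = 0.0587 (1 of 24) and Tmed6 0.0742 (3 of 24), and without young female replicate 5 Pnliprp2 reached 0.0994 (13 of 24).

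Were the age changes shared between cell types? Of 33 genes that rose in ISCs and were measured in progenitors, 12 also rose there, among them Ly6e, Ceacam10 and Zfp990. Independent lists would share 0.151 (Fisher p = 7.08e-21). Of 5 that fell, 4 also fell in progenitors, including Slc28a2, Nrn1 and Cdc42bpg (0.0128 expected, Fisher p = 1.71e-10), and none changed in the opposite direction. Paneth cells shared 4 risers with ISCs (Fisher p = 1.98e-09) and 3 with progenitors (Fisher p = 3.48e-06). These p-values treat the cell types as independent, while 23 of the 36 animal names gave more than 1 cell type. The rise of Ly6e was smaller in progenitors than in ISCs (difference -0.64 ± 0.12, edgeR adjusted p = 0.0201). Of 12680 genes only 5330417C22Rik, named because it passed, joined it (-1.39, edgeR adjusted p = 0.00491). With the animal as block the difference in Ly6e was -0.319 (edgeR adjusted p = 0.847) and no gene was called. In 6 of 43 fits that left out 1 sample it did not pass (highest edgeR adjusted p = 0.0771, without progenitor young female replicate 1). No gene differed in its age effect between Paneth cells and ISCs by edgeR (0 of 12863, 802 at unadjusted p below 0.05, DESeq2 3, limma-voom 1, edgeR with the animal as block 3). In that last comparison unscaled totals gave 3 genes, samples without ISC aged male replicate 3 gave 2 and those without Paneth aged male replicate 5 gave 1. The progenitor difference kept 1 gene without ISC young male replicate 1 or 4, ISC aged female replicate 1, progenitor young female replicate 1, progenitor aged male replicate 5 or progenitor aged female replicate 3. Lgr5 (-0.43 for Paneth cells and -0.043 for progenitors, each against ISCs), Olfm4 (-0.016 and -0.37), Mki67 (-0.11 and -0.21), Lyz1 (0.49 and 0.47) and Cd74 (0.0094 and -0.031) did not pass (lowest edgeR adjusted p = 0.871).

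**Figure D4:**
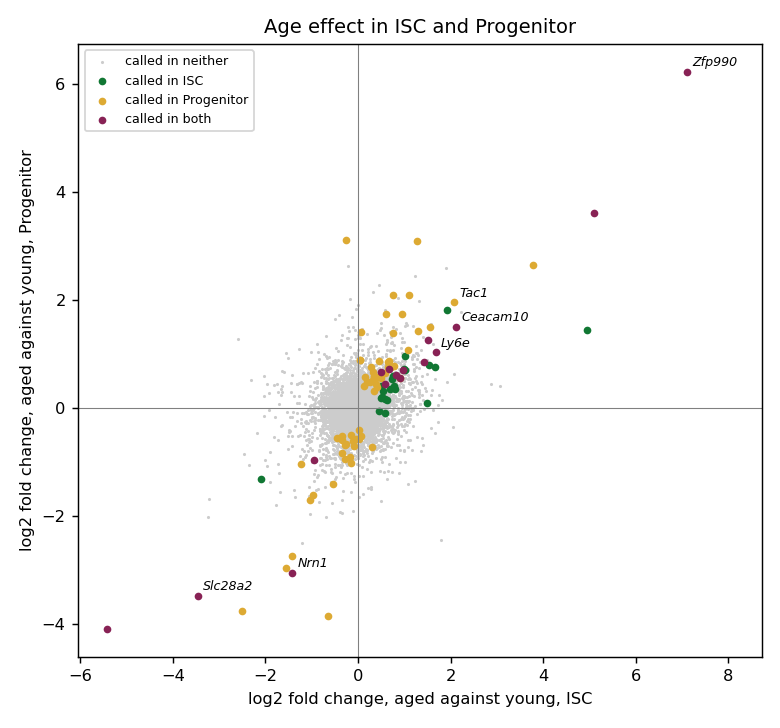
Log2 fold change, aged against young, of each gene in ISCs (x axis) and progenitors (y axis); grey points were called in neither, green in ISCs, yellow in progenitors and purple in both, with 6 genes labelled. Ly6e lay at 1.68 and 1.03, Slc28a2 at -3.47 and -3.47.

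Males and females were then tested apart. In ISCs of males (n = 7 aged, 5 young) 17 genes rose and 8 fell, with Ly6e, Ceacam10, Slc28a2, Wfdc2, Cdc42bpg, Nrn1, Foxd2os and Upb1 (log2 1.76, 2.24, -3.69, -3.40, -1.63, -1.81, 3.61 and 2.14, edgeR adjusted p = 4.79e-12, 0.00318, 0.00236, 0.0026, 0.00471, 0.0174, 0.0325 and 0.037). In ISCs of females (5 aged, 6 young) 8 rose and 1 fell, with Ly6e, Foxd2os, Fam20a, Ceacam10 and Slc28a2 (log2 1.59, 6.29, 2.10, 1.98 and -3.24, edgeR adjusted p = 6.39e-11, 0.000127, 0.00293, 0.0112 and 0.0211). In progenitors of males (5 and 5) 11 rose and 10 fell, with Nrn1, Card6, Phgdh, Slc28a2, Atf3, Iyd, Slc14a1 and Serpinb5 (log2 -4.85, 2.00, -1.25, -3.56, 3.30, 2.65, -2.15 and 2.94, edgeR adjusted p = 5.07e-05, 0.0165, 0.0178, 0.0186, 0.0271, 0.0345, 0.0364 and 0.0421). In those of females (5 and 5) 8 rose and 2 fell, with Ly6e, Parp3, Sulf2 and Slc28a2 (log2 1.13, 1.59, 2.42 and -3.38, edgeR adjusted p = 1.59e-06, 0.00754, 0.00996 and 0.0429). In Paneth cells of males (7 and 6) 3 rose and 1 fell, with Ceacam10, Dmbt1 and Ly6e (log2 2.81, -0.98 and 0.94, edgeR adjusted p = 7.18e-05, 0.000724 and 0.0235). In those of females (5 and 6) Ceacam10 and Ly6e (log2 2.17 and 1.02, edgeR adjusted p = 0.0172 and 0.0246) rose. With unscaled totals 57.1% rather than 80% of the genes called in female progenitors were higher and 100% rather than 75% of those in male Paneth cells. No gene differed between the sexes in its age effect by edgeR in ISCs, progenitors or Paneth cells (838, 731 and 621 at unadjusted p below 0.05, DESeq2 0, 2 and 0, limma-voom 0, 0 and 0). However, 8 ISC genes were called with the title number as block and 4 progenitor genes without the filter on low counts. Counts in 1 sex moved with single animals. Female ISCs gave 14 genes without young female replicate 6. Male progenitors gave 12 and 11 without young male replicates 1 and 3, 10 without aged male replicate 1 or 2 and 43 without aged male replicate 5. Female progenitors gave 6, 5 and 1 without young female replicates 1, 3 and 5 and 4 without aged female replicate 5. Male Paneth cells gave 2 genes without young male replicate 1 or 2 or aged male replicate 2. Female Paneth cells gave 0 without young female replicate 4 or 5 or aged female replicate 1, 2 or 4, and 1 without young female replicate 1 or 3 or aged female replicate 3. For age by sex in progenitors 1 gene was called without young female replicate 3 or aged male replicate 3.

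The markers followed in every comparison stayed uncalled with age in each sex. Male ISCs had Lgr5 0.10, Olfm4 0.34, Mki67 0.027, Lyz1 -0.16, Cd74 0.42, Ddx3y 0.94 (lowest edgeR adjusted p = 0.271). Female ISCs had Lgr5 -0.50, Olfm4 0.020, Mki67 -0.38, Lyz1 0.20, Cd74 0.18, Xist 0.39 (lowest edgeR adjusted p = 0.437). Male progenitors had Lgr5 0.47, Olfm4 0.0071, Mki67 -0.45, Lyz1 0.24, Cd74 0.61, Ddx3y 0.29 (lowest edgeR adjusted p = 0.403). Female progenitors had Lgr5 -1.05, Olfm4 -0.39, Mki67 -0.34, Lyz1 0.74, Cd74 -0.085, Xist -0.11 (lowest edgeR adjusted p = 0.557). Male Paneth cells had Lgr5 -0.40, Olfm4 0.47, Mki67 -0.20, Lyz1 0.22, Cd74 0.36, Ddx3y -0.71 (lowest edgeR adjusted p = 0.672). Female Paneth cells had Lgr5 -0.88, Olfm4 -0.18, Mki67 -0.40, Lyz1 0.75, Cd74 0.22, Xist -0.67 (lowest edgeR adjusted p = 0.76). Males minus females, the age effects differed in ISCs by Lgr5 0.60, Olfm4 0.32, Mki67 0.41, Lyz1 -0.36, Cd74 0.24 (lowest edgeR adjusted p = 0.603). In progenitors they differed by Lgr5 1.53, Olfm4 0.40, Mki67 -0.11, Lyz1 -0.50, Cd74 0.70 (lowest edgeR adjusted p = 0.795), and in Paneth cells by Lgr5 0.48, Olfm4 0.66, Mki67 0.20, Lyz1 -0.53, Cd74 0.14 (lowest edgeR adjusted p = 0.923). Without the males of 26 and 27 months 6 rather than 21 genes were called in male progenitors, and 4 with the description covariate. Of the 8 named there only Nrn1 then kept its call (lowest edgeR adjusted p of the others 0.569). Without these males Card6, Phgdh, Slc28a2, Iyd, Slc14a1 and Serpinb5 stood at 1.41, -0.865, -3.01, 2.41, -1.46 and 2.52, and Atf3 shrank from 3.30 to 1.23. In male ISCs 12 and 16 rather than 25 were called, and Wfdc2, Nrn1, Foxd2os and Upb1 lost their calls in both settings at similar folds (-2.90, -1.61, 3.37 and 1.99 without the oldest animals, lowest edgeR adjusted p = 0.086). Cdc42bpg lost its call with the title number as block (-1.62, edgeR adjusted p = 0.0636) and Ly6e in male Paneth cells without the oldest animals (0.913, edgeR adjusted p = 0.185). Male ISC calls of Nrn1, Foxd2os and Upb1 ended in 1, 9 and 6 of 23 fits that left out 1 animal (highest edgeR adjusted p = 0.11 without young male replicate 1, 0.109 without aged male replicate 1 and 0.116 without young male replicate 1). The female ISC call of Slc28a2 ended in 4 (highest edgeR adjusted p = 0.131, without aged female replicate 1). In male progenitors Card6, Phgdh, Slc28a2, Atf3, Iyd, Slc14a1 and Serpinb5 ended in 5, 4, 3, 6, 6, 6 and 13 of 20. The highest edgeR adjusted p was 0.0772 for Card6 without young male replicate 5 and 0.141 for Slc28a2 without young male replicate 3. It was 0.072, 0.131 and 0.205 for Phgdh, Iyd and Serpinb5 without aged male replicate 2, and 0.156 and 0.149 for Atf3 and Slc14a1 without aged male replicate 1. In female progenitors Parp3, Sulf2 and Slc28a2 ended in 1, 2 and 15 (highest edgeR adjusted p = 0.0658, 0.0814 and 0.124, each without young female replicate 5). Paneth calls of Ly6e in males and of Ceacam10 and Ly6e in females ended in 6, 5 and 8 of 24 (highest edgeR adjusted p = 0.116 without young male replicate 3, then 0.0971 and 0.198 without aged female replicate 4).

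Which genes differ between males and females at either age? Beyond the sex-linked genes, the cytokine signalling inhibitor gene Cish was lower in males in ISCs (-1.38 ± 0.29, edgeR adjusted p = 0.0401, n = 12 and 11) and in progenitors (-1.71 ± 0.28, edgeR adjusted p = 0.0016, n = 10 and 10). ISCs had 8 genes higher and 2 lower in males. Eif2s3y and Ddx3y stood at 96.6 and 22.6 CPM in males and 0.101 and 0.24 CPM in females, and Xist at 0.112 CPM in males (highest edgeR adjusted p = 1.80e-11). Besides Eif2s3y and Ddx3y, Rpl36a, Ubp1, Rpl22 and Rpl29 were higher in males (log2 0.63, 0.75, 0.47 and 0.41, edgeR adjusted p = 0.0223, 0.0312, 0.0401 and 0.0441). Progenitors had 5 higher and 11 lower, with Eif2s3y, Xist and Ddx3y (edgeR adjusted p = 6.80e-21, 2.72e-17 and 5.35e-15) and Olfm4, Slc40a1 and Nrn1 (log2 0.54, -1.26 and -1.87, edgeR adjusted p = 0.0127, 0.022 and 0.0312). Paneth cells differed in 3 genes, Eif2s3y and Xist (edgeR adjusted p = 1.71e-15 and 2.87e-12) among them, and Ddx3y did not pass (edgeR adjusted p = 0.0834). Of 25 lists 7 passed camera in ISCs and 5 in progenitors, and 7 of 26 in Paneth cells, and none of them with an estimated correlation. By sex, ISCs had Lgr5 -0.015, Olfm4 0.15, Mki67 -0.071, Lyz1 -0.35, Cd74 0.15 (lowest edgeR adjusted p = 0.741). Paneth cells had Lgr5 0.092, Olfm4 0.18, Mki67 0.15, Lyz1 -0.096, Cd74 0.32 (lowest edgeR adjusted p = 0.999). Progenitors had Lgr5 -0.16, Mki67 -0.054, Lyz1 -0.40 and Cd74 -0.050 (lowest edgeR adjusted p = 0.797). Rpl36a, Ubp1, Cish, Rpl22 and Rpl29 lost their ISC calls in 9, 13, 13, 15 and 18 of 23 fits that left out 1 animal. The highest edgeR adjusted p was 0.0952, 0.158 and 0.196 for Rpl36a, Rpl22 and Rpl29 without young male replicate 3, and 0.0856 and 0.125 for Ubp1 and Cish without aged female replicate 3. Slc40a1 and Nrn1 lost their progenitor calls in 9 and 13 of 20 (highest edgeR adjusted p = 0.0711 without young male replicate 5 and 0.0925 without aged male replicate 4). Without the animals of 26 and 27 months Olfm4 and Slc40a1 lost their progenitor calls (0.46 and -0.995, edgeR adjusted p = 0.405 and 0.852). With the description covariate Cish, Olfm4, Slc40a1 and Nrn1 did (-1.54, 0.46, -0.995 and -2.84, edgeR adjusted p = 0.112, 0.36, 0.807 and 0.0663). Ubp1, Rpl22 and Rpl29 lost their ISC calls in both at similar folds (0.636, 0.483 and 0.406 without these animals, lowest edgeR adjusted p = 0.0836). The ISC count fell from 10 to 6 without young male replicate 2 and to 5 without young male replicate 3, young female replicate 2 or 4, aged male replicate 6 or 7, or aged female replicate 3 or 5. The progenitor count went from 16 to 10 without young male replicate 5 and to 37 without young female replicate 4.

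A small set of genes thus changed with age in ISCs and progenitors. Slc28a2 and Nrn1 fell in both, and Ly6e and Ceacam10 rose in every gate. In progenitor samples of 5 young and 5 aged animals without an ISC sample, 34 of 38 ISC genes kept their sign. The exact binomial p of 6.04e-07 takes genes as independent. Lower Top2a, Ube2c and Aurka in aged progenitors would fit less proliferation or a shift in the cells that fall in the GFP medium to low gate. If other cell types in general filled more of the gate, enteroendocrine and goblet scores would move alike, and their difference did not pass (0.898, permutation test p = 0.0502). A larger share of other cells is therefore not excluded, and stromal and endothelial markers were higher in the same aged samples (48.2 against 21.5 CPM, adjusted permutation p = 0.042). The cell cycle median was -0.296 without the males of 26 and 27 months against -0.325 with them, and Top2a and Aurka kept most of their fold while losing their calls with fewer samples (-0.56 and -0.50, edgeR adjusted p = 0.0552 and 0.128). Cdc45 shrank from -0.51 to -0.384 (edgeR adjusted p = 0.394).

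The lean of H2-Aa, H2-DMa and H2-DMb1 in aged ISCs could be epithelial or from immune cells carried over despite the Epcam high, CD24 low gate. Immune markers differed by 42.1 CPM within sex (permutation test p = 0.234), H2-Aa by 192 CPM, and Cd74 was not called in any cell type. The class II median was 0.434 without aged female 2. The MHC class II score did not follow the stress score over 23 ISC animals (Pearson r = 0.0116, permutation p = 0.968).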

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

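Every group of animals was examined for a single value far from the rest of its group, and 27 of 218 groups held one where chance at about 1 in 20 would give 10.9. In ISCs, Ly6e had 480 CPM in young female 4 (next 366) and 1440 CPM in aged female 1 (next 1100), Foxd2os had 0 CPM in young male 3 (next 0.717) and 0.656 CPM in young female 1 (next 0.214) and Slc28a2 had 18.3 CPM in aged female 2 (next 4.06). Fam20a had 44 CPM in aged female 3 (next 24.7), Zfp990 had 0.185 CPM in young male 3 (next 0) and 0.214 CPM in young female 2 (next 0) and Wfdc2 had 4.93 CPM in young female 2 (next 16.8). Ddo had 11.7 CPM in young female 6 (next 5.07) and 45.2 CPM in aged male 3 (next 13.3) and 19.6 CPM in aged female 5 (next 12.3), Cd74 had 721 CPM in aged female 2 (next 398) and Ddx3y had 0.975 CPM in young female 6 (next 0.351) and 63.8 CPM in aged male 3 (next 30.7). Lyz1 had 655 CPM in young female 1 (next 265). In progenitors, Slc28a2 had 19.4 CPM in young male 3 (next 7.69), Serpinb5 had 0 CPM in young male 1 (next 1.17) and Fmo1 had 1.18 CPM in young male 1 (next 3.95). Iyd had 11.6 CPM in young female 5 (next 3.81), Atf3 had 9.07 CPM in young female 3 (next 3.54) and Tac1 had 32.9 CPM in young male 4 (next 11.9). Ddx3y had 10.6 CPM in young male 2 (next 23.8) and Cd74 had 455 CPM in young female 4 (next 275). In Paneth cells, Ceacam10 had 211 CPM in aged male 1 (next 125), Xist had 0.432 CPM in young male 1 (next 0.105) and Olfm4 had 1890 CPM in young female 1 (next 1190). The numbers after sex are the replicates of the titles. Aged female 2 of the ISCs, highest in Cd74 and Slc28a2, is also the sample richest in immune markers.

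No gene list differed in its age effect between sexes or cell types once the correlation within the list was estimated, although camera with the preset correlation called 30 such differences, given here as median log2 values, with the adjusted p at an estimated correlation after each camera p. In ISCs the male minus female difference was -0.908 for goblet markers, 0.427 for MHC class II, 0.312 for MHC class I and 0.589 for interferon genes (camera adjusted p = 5.6e-05, 0.0103, 0.0103 and 0.0103; adjusted p = 0.563, 0.563, 0.563 and 0.563). The same difference in ISCs was -0.175 for oxidative phosphorylation, -0.13 for ribosomal proteins, -0.225 for unfolded protein response and -0.419 for stress genes (camera adjusted p = 0.0103, 0.0388, 0.0108 and 0.0103; adjusted p = 0.668, 0.701, 0.521 and 0.654). In progenitors it was 0.443 for enterocyte markers, 0.827 for MHC class II, 0.346 for MHC class I and -0.151 for oxidative phosphorylation (camera adjusted p = 0.00219, 0.000845, 0.0016 and 0.0204; adjusted p = 0.809, 0.698, 0.698 and 0.809). Further in progenitors it was 0.309 for xenobiotic genes and 0.507 for stress genes (camera adjusted p = 0.0496 and 0.00447; adjusted p = 0.809 and 0.698). In Paneth cells it was -0.256 for Paneth markers, 0.471 for enterocyte markers, 1.48 for enteroendocrine markers and 0.519 for MHC class II (camera adjusted p = 0.0101, 0.00604, 3.52e-05 and 0.00773; adjusted p = 0.763, 0.763, 0.629 and 0.629). Further in Paneth cells it was -0.201 for ribosomal proteins, -0.368 for unfolded protein response and 0.92 for xenobiotic genes (camera adjusted p = 0.00982, 0.00902 and 3.52e-05; adjusted p = 0.763, 0.689 and 0.629). The progenitor minus ISC difference was -0.202 for cell cycle, -0.323 for interferon genes, 0.185 for fatty acid oxidation and 0.104 for ribosomal proteins (camera adjusted p = 2.1e-08, 0.043, 0.043 and 0.0166; adjusted p = 0.0912, 0.737, 0.756 and 0.756). The Paneth minus ISC difference was 0.435 for Paneth markers, -0.6 for tuft markers and -0.121 for oxidative phosphorylation (camera adjusted p = 0.00498, 0.0218 and 0.00498; adjusted p = 0.696, 0.696 and 0.696). Further against ISCs it was -0.26 for mitochondrial transcripts and -0.091 for ribosomal proteins (camera adjusted p = 0.0218 and 0.00498; adjusted p = 0.696 and 0.696). Among genes, Ly6e (-0.64; edgeR adjusted p = 0.0201) and 5330417C22Rik (-1.39; edgeR adjusted p = 0.00491) differed between progenitors and ISCs, while with the animal as block Ly6e was at -0.319 (edgeR adjusted p = 0.847) and no gene was called. The cause of these differences was not tested.

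For genes called in more than 1 cell type, the check on the description number in ISCs was chosen after the result had been seen. A chromosome segment that differed between the cohorts would place called genes side by side, and 21.4% of the 112 genes called in ISCs or progenitors lay within 1 Mb of another, against a median of 17.9% and a 95th percentile of 25.9% in random sets. The called genes were thus not closer together than chance allows, but a share inside the random range does not exclude segments that hold few of them, and neighbours such as Ehd1 and Cdc42bpg or H2-DMb1 and Psmb8 stay open. A difference between description numbers would remove calls. With that covariate 33 of 42 ISC but 31 of 86 progenitor calls stayed, leaving it open there. Sharing of animals would carry a signal from ISCs to progenitors. Yet 34 of 38 ISC genes, which are not independent, kept their sign in progenitor animals without an ISC library. For Ly6e, Ceacam10, Slc28a2 and Nrn1 a difference between the cohorts other than age stays open.

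For lower cell cycle and higher enteroendocrine genes in aged progenitors, the test of enteroendocrine against goblet scores was chosen after the result had been seen. If all other cell types made up more of the aged gate, enteroendocrine and goblet scores should not differ in their change, and by that test they did not (0.898, permutation test p = 0.0502), so this explanation is not excluded. After that p was seen, the wording of what the test should show was changed for a time so that it counted as undecided, and the first wording was then put back. The p lies next to the threshold and does not show that the scores moved alike. If the 3 males of 26 and 27 months drove it, the cell cycle median should shrink without them, and it was -0.296 against -0.325. These 3 males are also the progenitor samples that end in description number 2, so age and that number cannot be told apart there.

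For the upward lean of MHC class II genes in aged ISCs, the test of immune cells carried over was chosen after the result had been seen, as was leaving out the library richest in immune markers. Immune markers differed by 42.1 CPM within sex (permutation test p = 0.234), H2-Aa by 192 and Cd74 by 86.5 CPM. Without the immune-rich library the class II median was 0.434, not 0.601, so carry-over there explains part at most. Dissociation stress would raise both scores. Within groups they did not correlate (23 animals, Pearson r = 0.0116, permutation p = 0.968, Spearman rho = -0.0998, permutation p = 0.675, r = 0.0867 without the 2 farthest). A weak relation or shared age rise stays open.

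Animals were also regrouped at random within the design, and the splits that called at least as many genes as the real one, itself included, were counted out of 100. For age in ISCs this was 1 (42 genes, highest other 13), in males 2 (25, highest other 83) and in females 1 (9, highest other 4). Progenitors had 1 (86, highest other 2), with 1 (21, highest other 2) in males and 3 (10, highest other 29) in females. Paneth cells had 1 (8, highest other 2), with 1 (4, highest other 2) in males and 1 (2, highest other 1) in females. The sex effect had 1 (10, highest other 1) in ISCs, 1 (16, highest other 6) in progenitors and 1 (3, highest other 2) in Paneth cells. Age by sex had 100 (0, highest other 139) in ISCs, 100 (0, highest other 7) in progenitors and 100 (0, highest other 2) in Paneth cells. Paneth cells against ISCs had 1 (3763, highest other 1) and progenitors against ISCs 1 (3006, highest other 5). The difference of age effects had 3 (2, highest other 2) for progenitors and 100 (0, highest other 5) for Paneth cells. Counts above the real one cannot show structure beyond age and sex, as regrouped animals keep their age differences.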

How the results depend on the processing

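Alternative settings were run for every count of called genes and every named gene. Of alternative values of genes not called, 92 changed sign, 3612 kept their sign and stayed uncalled, and 77 became called. Of those of called genes 21 changed sign, 3071 kept sign and call, and 240 lost the call. Over all comparisons camera called 161 lists with the preset correlation, 23 with an estimated correlation and fry 51. The animal pairs samples by origin, but its block rests mainly on animals giving both cell types (10 for ISCs and progenitors), with less power. The cause of the moves below was not tested, except that fits with fewer samples or genes have less power. Leaving out mitochondrially encoded genes moved no count beyond 1.5 times, nor did leaving out the ISC library richest in immune markers.

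Counts moved beyond 1.5 times were these. DESeq2 called 1.1e+02 for age in ISCs, 87 in males and 22 in females, 25 by sex, 130 in progenitors, 61 in males, 35 in females, 2 for age by sex, 34 by sex, 36 in Paneth cells, 38 in males, 4 in females, 11 by sex and 3 for age in Paneth cells less ISCs. By limma-voom the counts were 11 and 25 in male and female ISCs, 13 in male progenitors, 4998 in progenitors against ISCs, and 1 and 1 for age in progenitors and Paneth cells less ISCs. The description covariate gave 16 and 17 in male and female ISCs, 1 for age by sex in ISCs, 34 in progenitors, 4 in their males and 6 by sex. Without the oldest animals (26 and 27 months) there were 12 in male ISCs, 34 in progenitors, 6 in their males, 8 by sex, 2 in Paneth cells, 2 in their males and 1 for age in Paneth cells less ISCs. The title number as replicate block gave 8 for age by sex in ISCs, 6 in female progenitors, 7 and 1 in male and female Paneth cells. The animal as replicate block gave 1617 in progenitors against ISCs, and 0 and 3 for age in progenitors and Paneth cells less ISCs. Unscaled totals gave 22 in Paneth cells, 1 in females, 11044 in Paneth cells against ISCs and 3 for age in Paneth cells less ISCs. Unfiltered, 4 genes were called for age by sex in progenitors, 1 in female Paneth cells and 5 by sex in Paneth cells. Technical library 1 alone gave 3 in Paneth cells, 2 in males, 0 in females, 1720 in progenitors against ISCs, which share a fit with the Paneth samples, and 2 for age in Paneth cells less ISCs.

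Fits that left out 1 animal gave 8 to 14 genes in female ISCs, 5 to 14 by sex in ISCs, 10 to 43 in male progenitors, 1 to 13 in female progenitors, 0 to 1 for age by sex in progenitors, 10 to 37 by sex in progenitors, 3 to 13 in Paneth cells, 2 to 6 in males and 0 to 2 in females among them. They gave 1 to 2 for age in progenitors less ISCs and 0 to 2 in Paneth cells less ISCs.

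Log2 values of genes that changed sign, with the title number or the animal as replicate block among the settings, were these, with the description number as the covariate, and ranges are over fits without 1 animal. Lyz1 with age in ISCs turned from 0.018 to -0.0065 unscaled, -0.28 by limma-voom, -0.21 with the title block, -0.12 with the covariate, -0.18 without the immune-rich library, range -0.18 to 0.28. Lgr5 with age in male ISCs turned from 0.10 to -0.021 with the title block. Lyz1 with age in male ISCs turned from -0.16 to 0.26 without the oldest. Mki67 with age in male ISCs turned from 0.027 to -0.015 by limma-voom, -0.17 without the oldest, range -0.091 to 0.20. Cd74 with age in female ISCs turned from 0.18 to -0.12 without the immune-rich library, range -0.12 to 0.30. Lyz1 with age in female ISCs turned from 0.20 to -0.014 by limma-voom, -0.036 with the title block, -0.00084 with the covariate, -0.20 without the immune-rich library, range -0.20 to 0.73. Olfm4 with age in female ISCs turned from 0.020 to -0.014 unscaled, -0.015 with the title block, -0.0064 without the immune-rich library, range -0.018 to 0.062. Ddx3y with age in female ISCs, where it lies at the floor of counting, was 0.12 and ran from -0.58 to 1.07. Ddx3y for age by sex in ISCs turned from 0.82 to -0.090 with the title block, range -0.12 to 1.52. Lyz1 for age by sex in ISCs turned from -0.36 to 0.068 without the oldest, 0.040 without the immune-rich library, range -0.90 to 0.040. Mki67 by sex in ISCs turned from -0.071 to 0.024 with the covariate, range -0.16 to 0.042. Lgr5 by sex in ISCs was -0.015 and ran from -0.071 to 0.039. Apoa4 with age in progenitors turned from 0.63 to -0.016 with the covariate and -0.013 without the oldest. Oas1a with age in progenitors turned from -0.40 to 0.021 with the covariate and 0.024 without the oldest. Lgr5 with age in male progenitors turned from 0.47 to -0.93 by limma-voom, -1.97 with the covariate and without the oldest, range -0.41 to 0.80. Lyz1 with age in male progenitors was 0.24 and ran from -0.041 to 0.45. Olfm4 with age in male progenitors turned from 0.0071 to -0.026 unscaled, -0.049 by limma-voom, -0.15 with the covariate and without the oldest, range -0.082 to 0.083. Xist with age in female progenitors was -0.11 and ran from -0.23 to 0.0094. Cd74 with age in female progenitors was -0.085 and ran from -0.19 to 0.13. Lgr5 for age by sex in progenitors turned from 1.53 to -0.92 with the covariate and without the oldest. Mki67 for age by sex in progenitors turned from -0.11 to 0.037 by limma-voom, range -0.23 to 0.040. Mki67 by sex in progenitors was -0.054 and ran from -0.12 to 0.020. Lgr5 by sex in progenitors was -0.16 and ran from -0.60 to 0.012. Cd74 by sex in progenitors turned from -0.050 to 0.17 with the covariate and without the oldest, range -0.20 to 0.057. Cdk1 with age in Paneth cells turned from -0.72 to 0.055 in technical library 1. Lgr5 with age in male Paneth cells turned from -0.40 to 0.048 in technical library 1. Mki67 with age in male Paneth cells turned from -0.20 to 0.080 unscaled and 0.13 without the oldest. Olfm4 with age in female Paneth cells was -0.18 and ran from -0.39 to 0.051. Mki67 for age by sex in Paneth cells was 0.20 and ran from -0.012 to 0.32. Cd74 for age by sex in Paneth cells was 0.14 and ran from -0.018 to 0.33. Ddx3y for age by sex in Paneth cells turned from -0.038 to 0.027 unscaled, range -0.60 to 0.66. Cd14 by sex in Paneth cells turned from 0.53 to -0.31 in technical library 1. Lyz1 by sex in Paneth cells was -0.096 and ran from -0.17 to 0.010. Lgr5 by sex in Paneth cells turned from 0.092 to -0.013 by limma-voom, range -0.036 to 0.36. Xist in Paneth cells against ISCs turned from 0.30 to -1.40 unscaled, range -0.41 to 0.67. Xist in progenitors against ISCs turned from -0.48 to 0.038 with the animal block. Cd74 for age in progenitors less ISCs turned from -0.031 to 0.056 by limma-voom, 0.31 with the animal block, 0.026 without the oldest, 0.12 without the immune-rich library, range -0.19 to 0.12. Lgr5 for age in progenitors less ISCs turned from -0.043 to 0.0038 with the animal block, range -0.53 to 0.13. Xist for age in progenitors less ISCs was -0.25 and ran from -0.65 to 0.22. Mki67 for age in Paneth cells less ISCs turned from -0.11 to 0.088 unscaled and 0.15 without the oldest. Olfm4 for age in Paneth cells less ISCs turned from -0.016 to 0.19 unscaled, 0.020 by limma-voom, 0.069 with the animal block, 0.091 without the oldest, range -0.12 to 0.10. Cd74 for age in Paneth cells less ISCs turned from 0.0094 to -0.0015 unfiltered, -0.011 by limma-voom, -0.0026 without mitochondrial genes, -0.047 without the oldest, range -0.096 to 0.16. Unscaled Paneth against ISC values turned below 0 for Anxa2 -0.22, Ces2e -0.058, Calr -0.62, Ifi27l2b -0.90, Ly6e -1.05, Klf4 -0.36, Ndufs7 -1.13 and Ndufb7 -0.99. Further such values were Uqcrq -0.90, Rpsa -1.23, Krt7 -1.26, Klf6 -0.61, Psmb10 -1.33, H2-T23 -0.84, Rpl13a -1.41 and Junb -0.92. Others were Mvk -0.80, Rfng -1.21, Nfkbia -1.16, Mvd -0.92 and Ddx3y -0.25.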

Other observations

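Cdkn1a and Cdkn2b, which encode inhibitors of cyclin-dependent kinases, were higher than in ISCs of young mice in progenitors (3.02 ± 0.36 and 5.18 ± 0.48; edgeR adjusted p = 3.49e-08 and 6.27e-10; n = 10 and 11) and in Paneth cells (4.35 ± 0.38 and 4.80 ± 0.47; edgeR adjusted p = 9.34e-12 and 1.63e-09), while the p53 target list did not pass (median -0.18, mean 0.088; camera adjusted p = 0.547). Bhlhe40 was higher in progenitors and Per2 and Nr1d2 differed too (1.68, -1.49 and -1.38; edgeR adjusted p = 5.87e-06, 0.00839 and 0.00729). Per2 lost its call with the animal as block (-1.35; edgeR adjusted p = 0.144) and Nr1d2 with the first technical library alone (-1.38; edgeR adjusted p = 0.114), and the circadian list was uncalled (median -0.016; camera adjusted p = 0.614).

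Afp, the alpha-fetoprotein gene, was among the largest changes in each comparison with ISCs, at 20.9 ± 14.7 CPM in progenitors and 178 ± 289.6 CPM in Paneth cells against 0.0662 ± 0.22 CPM in ISCs of young mice (edgeR adjusted p = 0.000178 and 1.39e-06). The progenitor call ended with the animal as block at a larger fold (9.15 against 8.39; edgeR adjusted p = 0.0918).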
